A study of Arabidopsis thaliana with 12 samples.

How the data were processed

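Messenger RNA of whole Arabidopsis seedlings was sequenced in 12 libraries, 3 for each combination of genotype (Col or fve-4) and temperature (21 or 27 °C). Per the labels' protocols, RNA was taken with the Eastep Super kit of Promega and libraries were made with the NEBNext Ultra RNA kit. The expression values are TPM (transcripts per 1000000), made by the authors from reads per gene and gene length and deposited as 1 table of 27655 genes. The column names of that table speak of gene counts, but each column sums to 1000000 and holds decimals, so the values were taken as TPM. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.1.10 and DESeq2 1.26.0 were used with the build TAIR10; the notes give no role or order for these tools, and no read counter or strand setting.

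The TPM values were checked for the reads behind them. All 23821 genes above 0 in any library gave whole read numbers in every library (tolerance 0.01). The length used was the gene span or, where that was missing or gave none, a length found from the values. It equalled the gene span for 99.98% of the genes with a span in the reference. On simulated tables the same step gave the right counts for 100% of 5991 genes. Levels are therefore not comparable between genes with long and short introns, since the median gene span was 1.31 times the exons. The recovered reads per library, from 11465313 to 14566380, are the depth given in the report. Gene symbols and lengths came from the RefSeq annotation of TAIR10.1, which held 99.24% of the gene identifiers; since its build is not named TAIR10, no coordinates are given and genes are identified by locus identifier.

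Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a variance prior following mean expression, on the 19863 genes with TPM of at least 1 in at least 3 libraries. One model of the 4 group means was fitted to all 12 libraries, with 8 residual degrees of freedom and no covariate. The 5 contrasts were 27 against 21 °C in Col, the same in fve-4, the difference of these changes (the interaction), and fve-4 against Col at each temperature. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast, and all tests were two-sided. Every adjusted p in the text comes from limma, from limma's camera or, where named, from limma-voom. Changes are differences of mean log2(TPM + 1) with standard errors, and TPM are means with SD.

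The 24 gene lists, with 348 members, were fixed beforehand from general knowledge of Arabidopsis. For each list the members called were counted, with adjustment over all genes tested and adjusted over the list alone. The 23 lists with at least 3 genes tested were compared with all other genes by camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast. The genes named were chosen by a rule with 4 parts. They were FVE and HDA9; 11 sentinels in every contrast whatever their result; up to 4 called list members per list, by smallest adjusted p, lists taken by camera p until about 20 genes; and the 5 largest rises and 5 largest falls per contrast among called genes with a symbol, a mean of at least 5 TPM in the higher group and, except for the interaction, no overlap between libraries. LOX2, ROS1, MGL, SEN5, IRT1 and the root hair genes EXPA7, PRP3 and LRX1 were named outside this rule.

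To measure the warm response without the bias of choosing genes on the same libraries, genes called and at least 2-fold changed were chosen without 1 replicate number and measured in the libraries left out, in 3 folds. Overlaps are given beside the number that independent lists would share, although the lists compared come from 1 fit with a shared estimate of the spread. Alternatives to the pseudocount, the filter, the scaling, the variance trend, the replicate block, the threshold, the libraries in the fit and each single library were planned, and limma-voom on recovered reads, TPM with exon lengths, and 2 more for the held-out response were added after seeing the data. Tests on single measures were exact or used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and drew figures.

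The tests were run on simulated libraries with the depth and means of these, with 200 genes changed in fve-4 at 27 °C. In fve-4 against Col at 27 °C, with 19784 genes tested, 66% of the genes changed 1.5-fold and 86% of those changed 2-fold were called, with 5 false calls. For the warm response of fve-4 these were 63% and 89% with 4 false calls, and for the interaction 46% and 72% with 10. In the 2 contrasts without change, 0 genes were called by limma. Far fewer genes were changed in these simulations than were called in the data (23.8% to 61.9% of those tested). The shares called and the false calls therefore need not carry over to the data. Mannitol samples, which the treatment protocol mentions, are not part of the series. Non-coding genes are not in the table. MYC2 was listed at 0 in all libraries and is not reported.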

Results

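Messenger RNA was sequenced from whole 7-day-old Arabidopsis seedlings of 2 genotypes, the wild type Columbia (Col) and fve-4, a mutant of FVE. FVE encodes a WD40-repeat protein of histone-modifying complexes. The seedlings were grown with 8 h of light and 16 h of dark. At ZT1 they were either moved from 21 °C to 27 °C or left at 21 °C, and all were harvested at ZT13, 12 h later. The 4 groups held 3 libraries each, and expression was given in TPM (transcripts per 1000000) for 27655 protein-coding genes. The reads recovered behind these values numbered between 11465313, in Col at 27 °C replicate 3, and 14566380, in Col at 21 °C replicate 3. The series asks what FVE contributes to the response to warm temperature. Mannitol treatment, which the design of the series also mentions, has no sample here and was not analysed. Of all variance in log2(TPM + 1), the first principal component held 54.6% and parted the temperatures, and the second held 18.6% and parted the genotypes. Col at 27 °C replicate 3 stood apart from its group, at 28.3 on the second component against 12.4 and 13.3. On the third component, fve-4 at 21 °C replicate 1 was at -27.4 against -21.1 and -15 for the rest of its group. On the first component, fve-4 at 27 °C replicate 1 was at 6.9 against 20.1 and 19.5.

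FVE itself was the first gene examined, since its level checks the genotype labels. At 21 °C FVE (AT2G19520) was at 52.7, 51.8 and 50.3 TPM in the Col libraries and at 4.9, 5.5 and 5.1 TPM in the fve-4 libraries. At 27 °C it was at 39.3, 41.6 and 39.9 TPM in Col and at 7, 6.8 and 6.6 TPM in fve-4. The fall in fve-4 was -3.10 ± 0.07 (SE) on the log2 scale at 21 °C (adjusted p = 4.07e-12) and -2.40 ± 0.07 at 27 °C (adjusted p = 1.84e-10). No library carried an FVE level of the other genotype. HDA9 (AT3G44680), the histone deacetylase that the title of the series pairs with FVE, differed between fve-4 and Col by 0.04 ± 0.08 (SE, log2) at 21 °C, which did not pass the test (adjusted p = 0.755). At 27 °C it was at 14.2 ± 1.3 and 15.6 ± 1.2 TPM (adjusted p = 0.243).

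**Figure D1:**
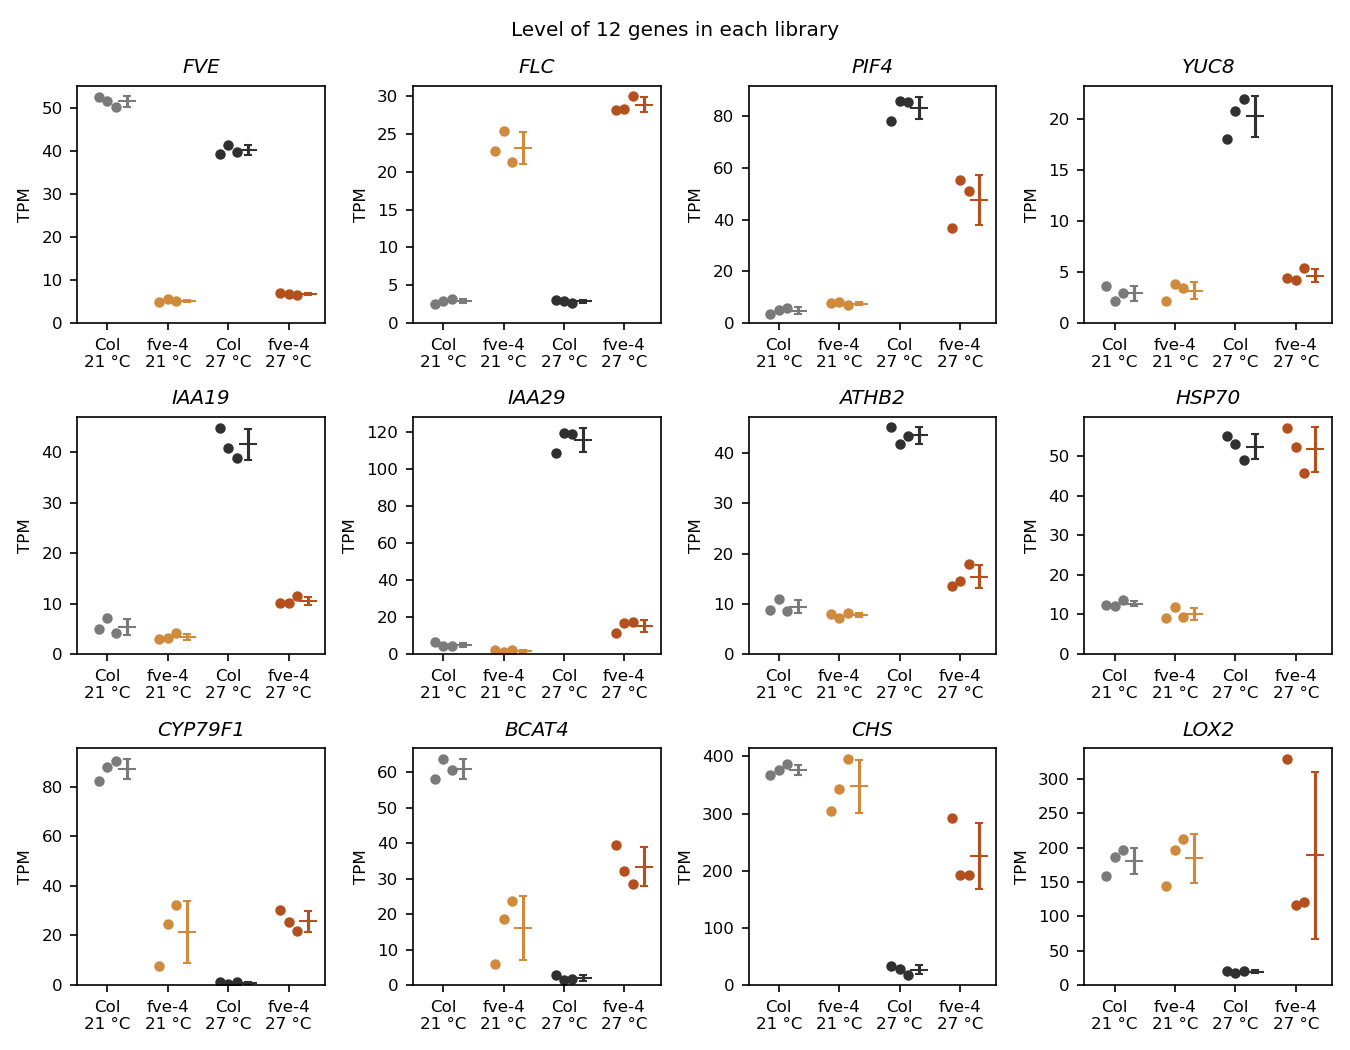
Level in TPM (vertical axis, linear from 0) of 12 genes in each library of Col and fve-4 at 21 °C and 27 °C (horizontal axis). Points are single libraries, and the bar beside them is the mean with its SD (n = 3); FVE lies below 10 TPM in every fve-4 library, IAA29 has a mean of 116 TPM in Col at 27 °C against 15.2 TPM in fve-4, and HSP70 means are 52.4 and 51.8 TPM.

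The comparison of 27 °C with 21 °C in Col asked what 12 h of warmth changed in the wild type. Auxin-response genes and targets of PIF factors rose. PIF4 (AT2G43010), a basic helix-loop-helix factor that promotes growth in warmth, rose from 4.76 ± 1.3 to 83.1 ± 4.4 TPM (SD, n = 3), and YUC8 (AT4G28720), an auxin synthesis enzyme, from 2.91 ± 0.73 to 20.3 ± 2 TPM. IAA29 (AT4G32280), an auxin-response repressor, rose from 5.06 ± 1.2 to 116 ± 6.3 TPM, a ratio of 22.9. Flavonoid and glucosinolate synthesis genes fell: DFR (AT5G42800) dropped from 39 ± 4.3 to 0.477 ± 0.15 TPM, and CYP83A1 (AT4G13770) from 239 ± 9.9 to 15.1 ± 2.2 TPM. COR15A (AT2G42540), a cold-regulated chloroplast protein, fell from 275 ± 31 to 2.06 ± 1.2 TPM.

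Of the 30 auxin-response genes tested, 28 rose in Col and 0 fell, over all genes tested and adjusted over the list alone. IAA2 rose by 2.36 on the log2 scale, GH3.5 by 1.85 and IAA7 by 1.64. The list moved up against all other genes by limma's camera test (adjusted p = 1.06e-09 with the preset correlation, adjusted p = 0.0242 with an estimated correlation). Among the 15 PIF and shade targets, 14 rose and 1 fell, by either adjustment. ATHB2 rose by 2.1, IAA19 of the auxin list by 2.75, LNG2 by 2.09 and HAT1 by 1.48, and the PIF list had an adjusted p of 1.26e-05 and adjusted p = 0.0186 with an estimated correlation. Of 19 circadian clock genes 15 rose and 0 fell, by either adjustment (adjusted p = 2.53e-06, and adjusted p = 0.0186 with an estimated correlation). LUX, a component of the evening complex, rose from 4.8 ± 0.32 to 69.5 ± 1.1 TPM, TOC1 from 55.8 ± 2.2 to 188 ± 11 TPM, and GI rose by 3.13 on the log2 scale. Of 20 heat-shock genes 16 rose and 3 fell, by either adjustment. HSP70 (AT3G12580) rose from 12.7 ± 0.71 to 52.4 ± 3.1 TPM and HSP101 from 6.97 ± 1 to 15.8 ± 1.4 TPM. The heat-shock list passed camera with the preset correlation (adjusted p = 0.0071) but not otherwise (adjusted p = 0.265 with an estimated correlation). Of 9 brassinosteroid synthesis genes 6 rose and 0 fell, by either adjustment (adjusted p = 0.0317, and adjusted p = 0.265 with an estimated correlation).

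All 13 flavonoid and anthocyanin genes tested fell in Col at 27 °C, also adjusted over the list alone. CHS, the entry enzyme of the pathway, dropped from 377 ± 9.1 to 26.7 ± 7.8 TPM, and GSTF12, which carries anthocyanin to the vacuole, from 41.7 ± 1.6 to 0.198 ± 0.11 TPM. The list's adjusted p was 7.24e-09, and adjusted p = 0.151 with an estimated correlation. Of 10 glucosinolate genes 9 fell and 1 rose, by either adjustment (adjusted p = 2.2e-06, and adjusted p = 0.265 with an estimated correlation). On the log2 scale CYP79F1 changed by -5.6, MAM1 by -3.6 and the regulator MYB28 by -0.96. Of 13 cell cycle genes 10 fell and 1 rose, by either adjustment (adjusted p = 0.00279, and adjusted p = 0.336 with an estimated correlation). Of 15 cold-acclimation genes 8 fell and 2 rose, by either adjustment (adjusted p = 0.00672, and adjusted p = 0.265 with an estimated correlation); COR15B fell by 5.28 on the log2 scale. Jasmonate-response genes had 5 of 8 lower and 0 higher, by either adjustment (adjusted p = 0.0176, and adjusted p = 0.356 with an estimated correlation). Root markers moved with these groups: 9 of 18 fell and 1 rose, by either adjustment (adjusted p = 0.0189, and adjusted p = 0.61 with an estimated correlation). Of the root hair genes, chosen after their values were seen, EXPA7 changed by -1.3, PRP3 by -0.81 and LRX1 by -0.75 on the log2 scale.

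The other lists did not pass camera in Col, and the median and mean of the abscisic acid list differed in sign (-0.16 and 0.02). Over all genes tested, 10 of 17 regulators of warm growth rose and 2 fell, and adjusted over the list alone 11 rose and 2 fell. Of 25 photosynthesis genes 14 rose and 8 fell, with 9 lower adjusted over the list alone. The following counts were the same by both adjustments. For FVE, HDA9 and their partners 4 of 10 rose and 4 fell, for the H2A.Z machinery 4 of 10 rose and 2 fell (4 and 4 by limma-voom), and for the FLC clade 1 of 6 rose. Floral promoters gave 2 higher and 1 lower of 5, auxin synthesis 3 and 3 of 8, wall growth 6 and 2 of 9, and abscisic acid and drought 4 and 6 of 12. Salicylic acid defence gave 1 higher and 4 lower of 13, seed maturation 3 higher and 0 lower of 9 (5 higher without fve-4 at 27 °C replicate 3), and the single silenced-locus gene tested, the demethylase gene ROS1, rose by 0.31. Among 9 reference genes 4 rose and 2 fell, so no reference gene was used for scaling. FLC was at 2.89 ± 0.31 TPM at 21 °C and 2.86 ± 0.24 TPM at 27 °C (adjusted p = 0.916), and SOC1, a promoter of flowering, fell from 5.48 ± 0.67 to 2.62 ± 0.5 TPM. FVE changed by -0.35 and HDA9 by -0.34 on the log2 scale.

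In total 7297 genes rose and 4990 fell in Col, 61.9% of the 19863 tested by limma with Benjamini-Hochberg adjustment, and 1081 and 767 of them by at least 2-fold. The share higher among the genes called was 59.4% on TPM as deposited, 49.9% after median-ratio rescaling, 50.8% after quantile normalization and 50.1% by limma-voom, so the excess of rises depended on the scaling. The named genes with the largest falls were COR15A, CYP79F1, LHCB1.1, COR15B and GSTF12, and those with the largest rises were ASN1 (from 4.72 ± 0.44 to 218 ± 10 TPM), AT4G35770, FLP1, RTFL21 and IAA29. LHCB1.1 is uncertain, because its reads can be shared with the near-identical LHCB1.2 and LHCB1.3; the same holds for the SAUR and MAF clusters, COR15A and COR15B, KIN1 and KIN2, CYP79F1 and its tandem copy, and CYP71A12 and its copy. Changes on the log2(TPM + 1) scale understate those of genes near or below 1 TPM, and p-values measure the spread between libraries, since the labels do not say whether replicates were separate cultures.

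In fve-4 the same shift to 27 °C raised auxin-response, PIF target, clock and heat-shock genes as well. PIF4 rose from 7.49 ± 0.57 to 47.7 ± 9.6 TPM, IAA29 from 1.71 ± 0.49 to 15.2 ± 3.5 TPM and IAA19 from 3.39 ± 0.65 to 10.6 ± 0.8 TPM (SD, n = 3). HSP70 rose from 10.1 ± 1.5 to 51.8 ± 5.7 TPM, and LUX from 6.06 ± 0.09 to 46 ± 2.3 TPM. Of 30 auxin-response genes 23 rose and 0 fell, of 15 PIF and shade targets 12 rose and 0 fell, and of 19 clock genes 17 rose and 0 fell, each by either adjustment. These lists had adjusted p of 2.23e-08, 9.19e-05 and 2.23e-08 by camera, and in the same order adjusted p = 0.0424, 0.0227 and 0.0135 with an estimated correlation. Of 20 heat-shock genes 15 rose and 0 fell (1 fell adjusted over the list alone), with an adjusted p of 9.19e-05 and adjusted p = 0.0924 with an estimated correlation. HSP90.1 rose by 2.31 on the log2 scale, HSP23.5 by 2.45 and the co-chaperone gene Hop3 by 2.85. Wall growth genes had 7 of 9 higher and 1 lower by either adjustment (adjusted p = 0.0128, and adjusted p = 0.0796 with an estimated correlation).

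Flavonoid genes fell in fve-4 too, 11 of 13 with 0 higher by either adjustment (adjusted p = 7.68e-09, and adjusted p = 0.0924 with an estimated correlation). DFR fell from 50.3 ± 6.9 to 5.54 ± 0.89 TPM and LDOX from 60.2 ± 1.6 to 16.3 ± 4.8 TPM. Of 15 cold-acclimation genes 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (adjusted p = 1.43e-05, and adjusted p = 0.0796 with an estimated correlation). COR15A changed by -4.97 on the log2 scale, KIN1 by -3.21 and LTI30 by -1.71. Glucosinolate genes had 1 of 10 higher and 1 lower by either adjustment, with a median of -0.02 and a mean of 0.09. The lower count was 3 without fve-4 at 21 °C replicate 1, after median-ratio rescaling and after quantile normalization, and 4 by limma-voom. None of the 18 root markers passed limma's test in fve-4 by either adjustment, 0 passed at an unadjusted p under 0.05, and 1 was lower by limma-voom on recovered reads.

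The lists that follow did not pass camera in fve-4, and for those of floral promoters, salicylic acid defence, the H2A.Z machinery and reference genes the sign of the median, the mean or the test differed. Regulators of warm growth gave 5 higher and 3 lower of 17 (3 higher without fve-4 at 27 °C replicate 2), and 6 and 4 adjusted over the list alone; after median-ratio rescaling, after quantile normalization and by limma-voom each gave 3 higher and 6 lower. Photosynthesis gave 13 and 6 of 25, with 7 lower adjusted over the list alone and 10 lower by limma-voom, and the H2A.Z machinery 3 and 1 of 10, with 2 lower adjusted over the list alone and 3 lower without fve-4 at 21 °C replicate 1, after median-ratio rescaling, after quantile normalization or by limma-voom. By both adjustments FVE and its partners gave 4 higher and 1 lower of 10, the FLC clade 2 and 2 of 6, floral promoters 1 and 1 of 5, auxin synthesis 2 and 1 of 8, and brassinosteroid synthesis 4 and 1 of 9. Abscisic acid and drought gave 1 and 5 of 12, salicylic acid defence 2 and 2 of 13, jasmonate response 1 and 2 of 8, seed maturation 2 and 0 of 9 (4 higher without fve-4 at 21 °C replicate 2, 0 without replicate 1 or 3), and reference genes 0 and 1 of 9. Cell cycle genes gave 1 higher and 5 lower of 13 by both adjustments. Without 1 library the lower count was 2 (fve-4 at 21 °C replicate 3) or 3 (fve-4 at 21 °C replicate 2 and each of the 3 fve-4 libraries at 27 °C). ROS1 rose by 0.75 on the log2 scale.

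In total 4998 genes rose and 2781 fell in fve-4, 39.2% of those tested, and 390 and 187 by at least 2-fold. The share higher among the genes called was 64.2% on TPM as deposited, 49.8% after median-ratio rescaling, 48.7% after quantile normalization and 49.5% by limma-voom. Among named genes, the largest falls were those of LHCB1.1, COR15A, COR15B, GSTF12 and KIN1, and the largest rises those of XTH25, RTFL21, Hop3, PCC1 and LUX. FVE rose by 0.35 from its low level, and SOC1 fell from 2.99 ± 0.34 to 0.468 ± 0.22 TPM. YUC8 was at 3.14 ± 0.83 and 4.66 ± 0.63 TPM (adjusted p = 0.0456), a call lost under 16 of 23 alternatives, at adjusted p up to 0.193 without fve-4 at 21 °C replicate 1 (range over alternatives 0.0278 to 0.193). Its call was also lost without Col at 21 °C replicate 3 (0.0563), Col at 27 °C replicates 1 and 2 (0.0521 and 0.0584), fve-4 at 21 °C replicate 3 (0.0571) and fve-4 at 27 °C replicates 1, 2 and 3 (0.0658, 0.0598 and 0.156). The FLC level in fve-4 was 23.2 ± 2.1 and 28.9 ± 0.97 TPM (adjusted p = 0.022). The FLC call was lost after median-ratio rescaling (0.0694), quantile normalization (0.0879), and without fve-4 at 21 °C replicates 1 and 3 (0.0597 and 0.0942) or fve-4 at 27 °C replicates 2 and 3 (0.0522 and 0.0805; range 0.00436 to 0.0942). HDA9 was at 18.7 ± 0.86 and 15.6 ± 1.2 TPM (adjusted p = 0.0226), a call lost without fve-4 at 21 °C replicates 1 and 2 (0.0654 and 0.0686) or fve-4 at 27 °C replicates 2 and 3 (0.0633 and 0.0958; range 0.00189 to 0.0958).

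**Figure D2:**
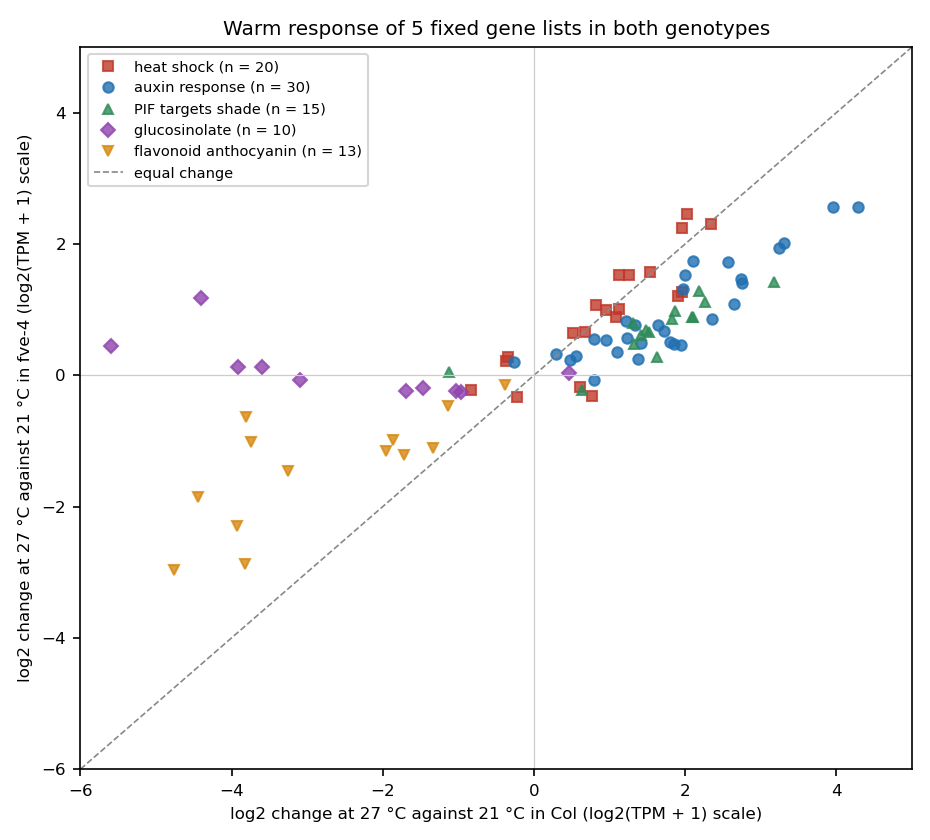
Log2 change from 21 °C to 27 °C in Col (horizontal axis) against that in fve-4 (vertical axis), on the log2(TPM + 1) scale, for the tested members of 5 gene lists; the dashed line marks equal change. Auxin-response genes (30) and PIF targets (15) lie mostly between the horizontal axis and the line, with medians of 1.76 and 1.63 in Col and 0.72 and 0.80 in fve-4, whereas heat-shock genes (20) have medians of 1.02 and 1 and glucosinolate genes (10) medians of -2.39 and -0.02.

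The interaction asked whether the response to warmth differed between the genotypes, as the change in fve-4 minus the change in Col. Members of the auxin-response and PIF target lists rose less in fve-4, and members of the glucosinolate and flavonoid lists fell less. With an estimated correlation the PIF target list alone passed camera (adjusted p = 0.0197), against 0.0571 for auxin response, 0.163 for glucosinolates and 0.222 for flavonoids. YUC8 had an interaction of -2.00 ± 0.24 (SE, log2; adjusted p = 6.4e-05), IAA29 of -1.72 ± 0.25, PIF4 of -1.39 ± 0.23, IAA19 of -1.35 ± 0.22 and ATHB2 of -1.21 ± 0.15. CYP79F1 had an interaction of 6.04 ± 0.49 (adjusted p = 4.77e-06), BCAT4 of 5.58 ± 0.48 and CHS of 3.17 ± 0.27. HSP70 was at 0.29 ± 0.14 (adjusted p = 0.132; 0.0291 without fve-4 at 21 °C replicate 2, range over alternatives 0.0291 to 0.279) and HSP101 at -0.19 ± 0.17 (adjusted p = 0.41).

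Of 30 auxin-response genes 19 had a negative interaction and 0 a positive one, and 20 and 0 adjusted over the list alone (adjusted p = 1.47e-08, and adjusted p = 0.0571 with an estimated correlation); by limma-voom 12 were negative and 0 positive. IAA2 was at -1.50 and GH3.5 at -1.39. Of 15 PIF and shade targets 13 were negative and 1 positive by either adjustment (adjusted p = 7.52e-06, and adjusted p = 0.0197 with an estimated correlation), with LNG2 at -1.2 and LNG1 at -0.81. After quantile normalization 11 were negative and 1 positive, and by limma-voom 9 and 1. Regulators of warm growth gave 10 negative and 2 positive of 17, and 12 and 2 adjusted over the list alone (adjusted p = 0.00623, and adjusted p = 0.222 with an estimated correlation). Clock genes gave 10 negative and 1 positive of 19, and 10 and 2 adjusted over the list alone (adjusted p = 0.00303, and adjusted p = 0.113 with an estimated correlation). Brassinosteroid synthesis gave 4 negative and 0 positive of 9 by either adjustment (adjusted p = 0.0374, and adjusted p = 0.287 with an estimated correlation). Heat-shock genes gave 2 of 20 in each direction by either adjustment and did not pass camera (adjusted p = 0.613).

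Glucosinolate genes gave 9 positive and 0 negative interactions of 10, with 1 negative adjusted over the list alone (adjusted p = 9.32e-09, and adjusted p = 0.163 with an estimated correlation). CYP83A1 was at 4.03 and MAM1 at 3.73, and IPMI1 and AK3, which act in the synthesis of leucine-like and methionine precursors, at 4.66 and 4.63. Flavonoid genes gave 9 positive and 0 negative of 13 by either adjustment (adjusted p = 1.76e-06, and adjusted p = 0.222 with an estimated correlation), with LDOX at 2.59, FLS1 at 2.73 and DFR at 1.79. Jasmonate-response genes gave 3 and 0 of 8 by either adjustment (adjusted p = 0.0235, and adjusted p = 0.501 with an estimated correlation). LOX2, a jasmonate synthesis enzyme chosen after its values were seen, was at 180 ± 19 and 19.4 ± 1.8 TPM in Col and at 185 ± 36 and 189 ± 120 TPM in fve-4. Its fve-4 libraries at 27 °C were at 329.52, 116.55 and 120.26 TPM. Without fve-4 at 27 °C replicate 1 their mean was 118 TPM, and the change in fve-4, not called with all libraries (-0.13, adjusted p = 0.759), was called (-0.62, adjusted p = 0.00325), while the interaction was called both with all libraries (3.02) and without it (2.53, adjusted p = 3.83e-06). Cell cycle genes gave 7 and 0 of 13 by either adjustment (adjusted p = 0.000922, and adjusted p = 0.333 with an estimated correlation), with PCNA1 at 0.93, RNR2A at 0.81, TSO2 at 0.73 and CYCD3;1 at 0.46. Root markers moved with these lists: 4 of 18 were positive and 1 negative, or 2 and 0 adjusted over the list alone (adjusted p = 0.0263, and adjusted p = 0.681 with an estimated correlation). The 4 became 2 without any 1 of the Col libraries at 21 °C, without fve-4 at 21 °C replicate 1 or 3, or without fve-4 at 27 °C replicate 1.

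For the remaining lists camera did not call an interaction, and the median and mean of FVE and its partners differed in sign (-0.07 and 0.04). By both adjustments FVE and its partners gave 2 positive and 2 negative of 10, the H2A.Z machinery 2 and 4 of 10, the FLC clade 1 and 2 of 6, wall growth 2 and 1 of 9, cold acclimation 4 and 2 of 15, and abscisic acid and drought 2 and 3 of 12. Photosynthesis gave 6 and 8 of 25, reference genes 2 and 3 of 9, and ROS1 was at 0.44. Floral promoters gave 0 and 1 of 5 (0 and 3 adjusted over the list alone), auxin synthesis 2 and 2 of 8 (2 and 3 adjusted over the list alone) and salicylic acid defence 4 and 1 of 13 (5 and 1 adjusted over the list alone). No seed maturation gene of 9 passed limma's test by either adjustment, and 0 passed at an unadjusted p under 0.05 or by limma-voom, but 3 were negative without fve-4 at 27 °C replicate 3. FLC was at 0.32 ± 0.14 (adjusted p = 0.09; 0.0406 with a pseudocount of 5 and 0.0495 with TPM from exon lengths, range over alternatives 0.0406 to 0.312) and SOC1 at -0.61 ± 0.23 (adjusted p = 0.0602, range 0.00511 to 0.553). SOC1 passed under 7 of 22 alternatives, among them without Col at 27 °C replicate 1 (0.0336) and without fve-4 at 27 °C replicate 1 (0.0425). HDA9 was at 0.08 ± 0.11 (adjusted p = 0.62), FVE at 0.70 and COR15A at 1.60.

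In total 6436 genes (32.4% of those tested by limma) had an interaction, 2851 positive and 3585 negative, and 852 of at least 2-fold. The share positive was 44.3% on TPM as deposited, 49.2% after median-ratio rescaling, 47.8% after quantile normalization and 48.9% by limma-voom. The most negative named genes were BCAT-2 (-3.63), AT4G35770 (-3.47), ASN1 (-2.88), UMAMIT33 (-2.85) and FLP1 (-2.77), and the most positive were CYP79F1, BCAT4, CYP82C4 (5.09), IPMI1 and AK3. The FLP1 call (adjusted p = 0.000921) was lost at a pseudocount of 0.1 (0.152) and by limma-voom (0.103; range over alternatives 1.5e-05 to 0.152).

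The size of the warm response was also measured on genes chosen without the libraries used to measure it. Genes at least 2-fold higher in Col, chosen without 1 replicate number of Col (3 folds, about 1112 genes), had a median change of 1.24 ± 0.03 in the left-out Col libraries and of 0.62 ± 0.02 in fve-4 (SD over 3 folds). The fve-4 change was 50.1% ± 0.8 of that in Col. For genes at least 2-fold lower (about 805) the medians were -1.21 ± 0.16 and -0.41 ± 0.05, a share of 34% ± 0.8. The same fve-4 libraries were used in every fold, so the SD of these shares leaves out the spread between fve-4 replicates. Without 1 fve-4 replicate number the share ranged from 46.4% to 55.4% for higher genes and from 28.8% to 43.4% for lower genes. In simulated libraries with equal responses the shares were 98.2% and 97.5%. Noise was drawn there for each gene apart, so these shares do not show how far shifts shared across a library can move them. Genes chosen in fve-4 in the same way gave 1.15 ± 0.17 in left-out fve-4 libraries and 1.2 ± 0.11 in Col for higher genes (about 406), and -1.09 ± 0.25 and -1 ± 0.07 for lower genes (about 208). By fold, Col reached 88.5% to 137.8% of the left-out fve-4 change for higher genes and 76.1% to 133.9% for lower ones. Of the genes higher in Col and those higher in fve-4, 3889 were shared where independent lists would share 1836, and of the lower genes 2068 were shared where 699 would be. Genes called in opposite directions numbered 151 among those higher in Col and 222 among those lower. Across genes, which are not independent replicates, the changes of the genotypes correlated with Pearson's r = 0.61.

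At 21 °C the comparison of fve-4 with Col asked what the mutation changed without warming. FLC (AT5G10140), the repressor of flowering, rose from 2.89 ± 0.31 to 23.2 ± 2.1 TPM (SD, n = 3; adjusted p = 1.83e-09), with MAF4, MAF5 and MAF2 of its clade. Glucosinolate genes fell: CYP79F1 dropped from 87 ± 4.1 to 21.6 ± 13 TPM and BCAT4 from 60.9 ± 2.8 to 16.1 ± 9.1 TPM. ASN1, an asparagine synthetase induced in the dark, rose from 4.72 ± 0.44 to 43.3 ± 19 TPM. AT4G35770, also dark-induced, rose from 22.2 ± 2 to 246 ± 89 TPM.

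Of the 6 FLC clade genes 4 rose and 0 fell, by either adjustment (adjusted p = 0.00125, and adjusted p = 0.126 with an estimated correlation), by 2.63 for FLC, 1.28 for MAF5, 0.85 for MAF4 and 0.43 for MAF2 on the log2 scale. The TPM of FLC rests on its gene span of 6067 bp, 5.14 times its exons, so its level is low beside other genes and the pseudocount shrinks its change; with exon lengths the change at 21 °C was 2.89 on the log2 scale. Of 10 glucosinolate genes 8 fell and 0 rose, by either adjustment (adjusted p = 1.47e-07, and adjusted p = 0.334 with an estimated correlation). Auxin-response genes gave 6 lower and 2 higher of 30, and 6 and 4 adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.334 with an estimated correlation). The 6 became 3 without fve-4 at 21 °C replicate 1, and the 2 became 4 without fve-4 at 27 °C replicate 1 and 0 without Col at 21 °C replicate 3 or fve-4 at 21 °C replicate 1 or 2. After median-ratio rescaling the counts were 6 lower and 0 higher, and by limma-voom 3 and 1. IAA29 changed by -1.16 and GH3.6 by -0.33. Of 13 cell cycle genes 4 fell, and 5 adjusted over the list alone, with 0 higher (adjusted p = 0.000554, and adjusted p = 0.334 with an estimated correlation). TSO2 changed by -0.43 and KNOLLE by -0.42. The 4 became 2 without Col at 21 °C replicate 1 or 2 or fve-4 at 21 °C replicate 1.

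None of the other lists passed camera at 21 °C, and the sign of the median, the mean or the test differed for FVE and its partners, wall growth, brassinosteroid synthesis, abscisic acid, jasmonate, seed maturation and reference genes. By both adjustments FVE and its partners gave 2 higher and 1 lower of 10, floral promoters 2 and 1 of 5, auxin synthesis 0 and 3 of 8, PIF and shade targets 0 and 2 of 15, brassinosteroid synthesis 0 and 1 of 9, salicylic acid defence 4 and 0 of 13, jasmonate response 1 and 1 of 8, and seed maturation 1 and 1 of 9. The H2A.Z machinery gave 2 and 0 of 10 (2 and 1 adjusted over the list alone), wall growth 1 and 3 of 9 (2 and 3), heat shock 4 and 2 of 20 (6 and 2), abscisic acid and drought 2 and 1 of 12 (2 and 3, as after median-ratio rescaling and by limma-voom), root markers 0 and 1 of 18 (0 and 0) and reference genes 1 and 1 of 9 (1 and 2). ROS1 fell by 0.50. CYP79B2 and CYP79B3, which start indole glucosinolate synthesis, changed by -0.96 and -0.86. RD29A changed by -1.11 and KIN2 by -0.81. Without fve-4 at 21 °C replicate 1, 0 floral promoters were higher and 0 heat-shock genes lower, and without fve-4 at 27 °C replicate 1, 3 wall growth genes were higher. Counts of the lists named next also moved by over 1.5 times without a library of 21 °C. Regulators of warm growth gave 5 and 0 of 17 by both adjustments, but 3 and 2 after median-ratio rescaling, 2 and 1 after quantile normalization and 2 and 2 by limma-voom. The higher count was 2 without fve-4 replicate 2 and 3 without Col replicate 1 or 3 or fve-4 replicate 1 or 3. Cold acclimation gave 4 and 5 of 15 by both adjustments, with 0 higher without Col replicate 3 or fve-4 replicate 2, 1 without Col replicate 2, and 2 without Col replicate 1 or fve-4 replicate 1 or 3; limma-voom gave 2 and 7. Clock genes gave 6 and 2 of 19 (7 and 2 adjusted over the list alone), and 3 and 2 after quantile normalization or by limma-voom. Of these genes 3 were higher without Col replicate 3 or fve-4 replicate 1, and 0 lower without Col replicate 2 or 3 or fve-4 replicate 1 or 3. Flavonoid genes gave 0 and 4 of 13 (1 and 4), and 2 and 5 by limma-voom, and the lower count was 1 without Col replicate 2 or fve-4 replicate 2 and 2 without Col replicate 1 or 3 or fve-4 replicate 1. Photosynthesis gave 5 and 7 of 25 (6 and 8), with 1 and 8 after median-ratio rescaling, 3 and 3 after quantile normalization and 2 and 9 by limma-voom. Its higher count was 2 without Col replicate 2 or fve-4 replicate 3 and 3 without Col replicate 1 or fve-4 replicate 1, and its lower count was 3 without Col replicate 3 or fve-4 replicate 1 and 4 without Col replicate 2.

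In total 3039 genes were higher and 1687 lower in fve-4 at 21 °C, 23.8% of those tested by limma, and 241 and 75 by at least 2-fold. The lower genes numbered 1083 without fve-4 at 21 °C replicate 1 and 2723 by limma-voom. The share higher was 64.3% on TPM as deposited, 47.9% after median-ratio rescaling, 50.2% after quantile normalization and 45.5% by limma-voom, while the named genes with the largest changes kept their direction under each. These were the falls of FVE, PnsL4 (a subunit of the chloroplast NDH complex, from 116 ± 3.7 to 18.3 ± 1.3 TPM), IMS2, CYP79F1 and BCAT4, and the rises of AT4G35770, QQS (from 3.17 ± 0.36 to 37.8 ± 3.5 TPM), ASN1, FLC and CYP71A12. FT was listed at 0 in 11 of the 12 libraries and at 0.118 TPM in Col at 21 °C replicate 3, too low for the test. SOC1 fell from 5.48 ± 0.67 to 2.99 ± 0.34 TPM (adjusted p = 0.00812), a call lost at a pseudocount of 0.1 (0.0508; range over alternatives 0.000564 to 0.0508).

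The calls of 9 further named genes at 21 °C were lost without single libraries, while the direction of each change stayed the same. With all libraries, HSP70, COR15A and CDKB1;1 also lost the call without the variance trend, and SAUR21 with a pseudocount of 5. PIF4 was at 4.76 ± 1.3 TPM in Col and 7.49 ± 0.57 TPM in fve-4 (adjusted p = 0.0187), with 0.0708 without Col replicate 1, 0.0557 and 0.0638 without fve-4 replicates 1 and 2, and 0.0868 by limma-voom (range over alternatives 0.00787 to 0.0868). IAA19 was at 5.43 ± 1.6 and 3.39 ± 0.65 TPM (adjusted p = 0.0238), with 0.0935 without Col replicate 2 and 0.0884 and 0.0767 without fve-4 replicates 1 and 2 (range 0.00819 to 0.0935). HSP70 was at 12.7 ± 0.71 and 10.1 ± 1.5 TPM (adjusted p = 0.0361). Without Col replicates 1, 2 and 3 its adjusted p was 0.0676, 0.058 and 0.121, and without fve-4 replicates 1 and 3 it was 0.13 and 0.11 (range 0.00879 to 0.13). COR15A was at 275 ± 31 and 169 ± 36 TPM (adjusted p = 0.047), a call lost under 12 of 23 alternatives, among them without each of the 6 libraries of 21 °C (0.0562 to 0.181), without Col at 27 °C replicate 1 (0.0573) and without fve-4 at 27 °C replicate 3 (0.0588; range 3.42e-05 to 0.181). For PCNA1 (adjusted p = 0.0243) the call was lost without Col replicates 1 and 2 (0.0835 and 0.0556) and fve-4 replicates 1 and 2 (0.098 and 0.0534; range 0.00221 to 0.098). For CDKB1;1 (0.0312) it was lost without Col replicates 1 and 2 (0.127 and 0.0561) and fve-4 replicates 1 and 3 (0.116 and 0.0603; range 0.00457 to 0.127). For SAUR21 (0.0232) it was lost without Col replicates 1 and 2 (0.0997 and 0.0547) and fve-4 replicates 1 and 3 (0.0969 and 0.0613), and by limma-voom (0.0841; range 0.00636 to 0.0997). For YUC2 (0.0182) it was lost without Col replicate 3 (0.0757) and fve-4 replicates 1 and 2 (0.0509 and 0.0593; range 0.00423 to 0.0757), and for SAUR66 (0.0116) without Col replicate 3 (0.0535) and by limma-voom (0.0553; range 0.00272 to 0.0553). YUC8, ATHB2 and HSP101 were not called (adjusted p = 0.774, 0.131 and 0.963).

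At 27 °C the comparison of fve-4 with Col asked how the genotypes differed after warming. Auxin and PIF target genes were lower in fve-4. IAA29 was at 116 ± 6.3 TPM in Col and 15.2 ± 3.5 TPM in fve-4, YUC8 at 20.3 ± 2 and 4.66 ± 0.63 TPM, IAA19 at 41.6 ± 3.1 and 10.6 ± 0.8 TPM, and ATHB2 at 43.6 ± 1.7 and 15.4 ± 2.3 TPM (SD, n = 3). PIF4 was also lower, at 83.1 ± 4.4 and 47.7 ± 9.6 TPM (adjusted p = 0.00165). Glucosinolate and flavonoid genes were higher in fve-4, with CYP79F1 at 0.837 ± 0.35 and 25.7 ± 4.3 TPM and CHS at 26.7 ± 7.8 and 225 ± 57 TPM. FLC was at 2.86 ± 0.24 and 28.9 ± 0.97 TPM, and SOC1 at 2.62 ± 0.5 and 0.468 ± 0.22 TPM.

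Of 30 auxin-response genes 26 were lower and 0 higher, by either adjustment (adjusted p = 6.31e-16, and adjusted p = 0.00789 with an estimated correlation), among them IAA2 by -1.33, GH3.5 by -1.2 and IAA7 by -0.95 on the log2 scale. Of 15 PIF and shade targets 14 were lower and 1 higher, by either adjustment (adjusted p = 3.14e-09, and adjusted p = 0.00336 with an estimated correlation). The differences were -1.89 for HFR1, -1.2 for LNG2, -1.09 for HAT2 and -1.99 for the ethylene synthesis gene ACS8. Clock genes gave 12 lower and 1 higher of 19, by either adjustment (adjusted p = 0.000195, and adjusted p = 0.0413 with an estimated correlation), and 7 lower without Col at 27 °C replicate 3. PRR7 differed by -1.77, CDF5 by -1.42, LUX by -0.59 and ELF4 by 0.89. Regulators of warm growth gave 8 lower and 2 higher of 17 (adjusted p = 0.00519, and adjusted p = 0.23 with an estimated correlation), brassinosteroid synthesis 4 and 0 of 9 (adjusted p = 0.0163, and adjusted p = 0.23 with an estimated correlation), and photosynthesis 11 and 3 of 25 (adjusted p = 0.0135, and adjusted p = 0.499 with an estimated correlation), each by either adjustment.

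Glucosinolate genes gave 9 higher and 1 lower of 10, by either adjustment (adjusted p = 7.41e-06, and adjusted p = 0.23 with an estimated correlation), with BCAT4 higher by 3.54 and CYP83A1 by 2.84. Flavonoid genes gave 10 higher and 1 lower of 13, and 11 and 1 adjusted over the list alone (adjusted p = 3.64e-05, and adjusted p = 0.237 with an estimated correlation). LDOX was higher by 3.01, DFR by 2.14 and FLS1 by 2.12. Jasmonate-response genes gave 5 and 0 of 8, and 6 and 0 adjusted over the list alone (adjusted p = 0.00853, and adjusted p = 0.36 with an estimated correlation). Salicylic acid defence gave 7 and 0 of 13 by either adjustment (adjusted p = 0.0101, and adjusted p = 0.136 with an estimated correlation). PCC1, a defence- and clock-regulated gene, was at 0.502 ± 0.41 TPM in Col and 48.3 ± 11 TPM in fve-4. Root markers moved with these groups: 12 of 18 were higher and 1 lower, by either adjustment (adjusted p = 0.00519, and adjusted p = 0.499 with an estimated correlation), but 5 were higher without fve-4 at 27 °C replicate 1 and 6 without Col at 27 °C replicate 3 or after quantile normalization.

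Lists without a camera call at 27 °C gave these counts by both adjustments unless stated, and the sign of the median, the mean or the test differed for FVE and its partners, the H2A.Z machinery, floral promoters and cold acclimation. FVE and its partners gave 2 higher and 2 lower of 10, the H2A.Z machinery 2 and 2 of 10, the FLC clade 3 and 1 of 6, floral promoters 1 and 1 of 5, auxin synthesis 1 and 3 of 8, heat shock 5 and 0 of 20 (7 and 2 by limma-voom), abscisic acid and drought 3 and 3 of 12, cell cycle 6 and 1 of 13, and reference genes 1 and 3 of 9. Wall growth gave 2 and 4 of 9, with 4 higher without fve-4 at 27 °C replicate 1. Seed maturation gave 1 and 1 of 9, with 4 lower without fve-4 at 27 °C replicate 3. Cold acclimation gave 3 and 4 of 15, or 4 and 4 adjusted over the list alone, with 1 higher without fve-4 at 27 °C replicate 1. Without Col at 27 °C replicate 1 or fve-4 at 27 °C replicate 1, 1 abscisic acid gene was higher, and without Col at 27 °C replicate 3, 0 genes of FVE and its partners were higher. ROS1 was not called, at -0.06. HSP70 and HSP101 were not called at 27 °C (-0.02 and -0.20, adjusted p = 0.887 and 0.193); HSP101 passed under 1 of 23 alternatives, with a range of 0.0496 to 0.409. COR15A was at 2.06 ± 1.2 and 4.41 ± 1.1 TPM (adjusted p = 0.0124). Its call was lost after quantile normalization (0.0601), by limma-voom (0.0937) and without Col replicate 2 (0.0522) or fve-4 replicate 1 (0.0518) of 27 °C, with a range of 0.00104 to 0.0937.

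In total 4158 genes were higher and 3490 lower in fve-4 at 27 °C, 38.5% of those tested by limma, and 512 and 165 by at least 2-fold. The share higher was 54.4% on TPM as deposited, but 48.6% after median-ratio rescaling, 46.3% after quantile normalization and 46.3% by limma-voom. The largest falls among named genes were those of FLP1, IAA29, ST2A, FVE and ACS8, and the largest rises those of PCC1, CYP79F1, MES18, ECS1 and BCAT4. Between the genotype differences at 21 °C and at 27 °C, which share no library, 709 higher genes were shared where independent lists would share 636, and 376 lower genes where 296 would be. Of the genes higher in fve-4 at 21 °C, 786 were lower at 27 °C (534 for independent lists), and of those lower at 21 °C, 511 were higher at 27 °C (353 for independent lists). Across genes, the differences correlated with Pearson's r = 0.13.

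**Figure D3:**
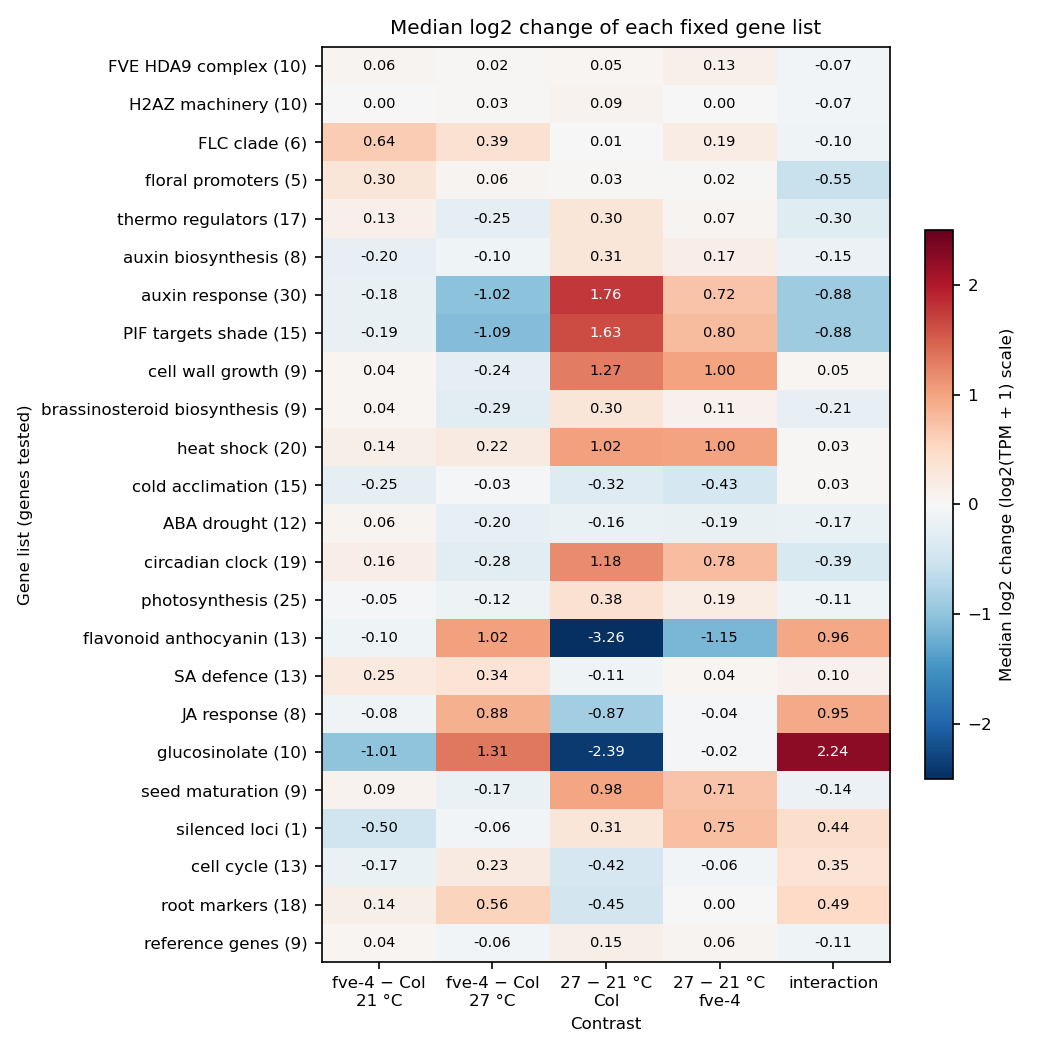
Median log2 change, on the log2(TPM + 1) scale, of each of the 24 gene lists (vertical axis, number of genes tested in brackets) in the 5 contrasts (horizontal axis); red is higher and blue lower. The glucosinolate list has medians of -1.01 and 1.31 in fve-4 against Col at 21 °C and 27 °C, and the auxin-response list medians of -0.18 and -1.02.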

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

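The tests on the choice of genes, the scaling and a weaker treatment were chosen only after the result was seen; the regroupings of libraries were planned. All results here were picked out because limma's interaction test called the response to 27 °C different between fve-4 and Col.

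The interaction called 6436 genes, and 5843 without Col at 27 °C replicate 3, 5678 without fve-4 at 21 °C replicate 1 and 5515 without fve-4 at 27 °C replicate 1, the libraries that lay apart from their groups. Among the gene lists, the median interaction (fve-4 minus Col, log2) was -0.30 for regulators of warm growth, -0.88 for auxin response, -0.88 for PIF and shade targets, -0.21 for brassinosteroid synthesis and -0.39 for the clock. It was 0.96 for flavonoids, 0.95 for jasmonate response, 2.24 for glucosinolates, 0.35 for the cell cycle and 0.49 for root markers. Of these lists, PIF and shade targets alone passed with an estimated correlation as well.

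Among growth genes the interaction was -1.39 for PIF4, -2 for YUC8, -1.35 for IAA19, -1.72 for IAA29, -1.21 for ATHB2, -1.5 for IAA2, -1.39 for GH3.5, -0.88 for IAA7, -0.76 for IAA4, -1.2 for LNG2, -0.81 for LNG1 and -0.79 for HAT1. Among glucosinolate genes and their precursor synthesis it was 4.03 for CYP83A1, 6.04 for CYP79F1, 3.73 for MAM1, 5.58 for BCAT4, 4.66 for IPMI1 and 4.63 for AK3. Among flavonoid genes it was 3.17 for CHS, 1.79 for DFR, 2.59 for LDOX and 2.73 for FLS1, and among cell cycle genes 0.73 for TSO2, 0.81 for RNR2A, 0.93 for PCNA1 and 0.46 for CYCD3;1. FVE had 0.70, COR15A 1.60 and CYP82C4 5.09, and BCAT-2 had -3.63, AT4G35770 -3.47, ASN1 -2.88, UMAMIT33 -2.85 and FLP1 -2.77.

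Of 100 regroupings of the libraries into genotypes within temperatures, 1, the real grouping, called as many as 6436 genes. Most regroupings mix the genotypes and so also break up a genotype difference that is alike at both temperatures. They therefore cannot exclude chance for the interaction alone. The highest other called 5813, and it exchanges the genotype names at 27 °C, so that it measures the mean genotype difference; the highest of the remaining regroupings called 2988.

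The smaller warm response in fve-4 was weighed against technical explanations. Choice of the genes by noise in the same Col libraries is argued against, since fve-4 reached at most 51% of the left-out Col response in any fold and direction. In the held-out measure, fve-4 responded less in every fold only for genes chosen in Col. Higher genes chosen in fve-4 changed by 1.15 in left-out fve-4 libraries and 1.2 in Col, and lower ones by -1.09 and -1. These are means over folds that disagreed. Col reached 137.8%, 93.6% and 88.5% of the left-out fve-4 response for higher genes, and 133.9%, 76.1% and 81.4% for lower ones. The first of each was measured on fve-4 replicate 1. Lists fixed beforehand also rose less in fve-4, with a median interaction of -0.88 for auxin response and -0.88 for PIF and shade targets. Scaling of the libraries is argued against by the fve-4 share of the Col response, at most 49.8% under median-ratio rescaling or quantile normalization. A weaker warm treatment of the fve-4 plants is argued against by heat-shock genes that rose in Col. These kept a median of 100.4% of their response in fve-4 (95% bootstrap interval over genes 81.8 to 120.2, 16 genes). Auxin-response genes that rose in Col kept 52.3% (41.2 to 60.3, 28 genes), and all genes at least 2-fold higher in Col 47.6% (46.3 to 48.8). Heat-shock and auxin genes differed by 48.1 (permutation p = 7e-05 across genes). Genes are not independent replicates, so the intervals and this p leave out the spread between libraries. Here genes were chosen and measured in the same Col libraries, and the 2-fold minimum was not asked of the lists. A weaker transcriptional response of auxin-response and PIF target genes to warmth without FVE may be a biological difference. This hypothesis was found and tested on the same data. A shift in the timing of the response, at 1 harvest time, was not tested.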

How the results depend on the processing

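Limma-voom on recovered reads, TPM with exon lengths, and quantile normalization and leaving out fve-4 replicates for the held-out response were chosen after seeing the data; the other alternatives were chosen before the data were examined. Under every alternative, 0 of the genes called were called in the opposite direction. Total counts of calls stayed within 1.5 times under each alternative except the added 2-fold threshold, which by construction left 316 genes for fve-4 against Col at 21 °C, 677 at 27 °C, 1848 for the warm response of Col, 577 for that of fve-4 and 852 for the interaction. By direction, the 1687 lower genes in fve-4 at 21 °C became 2723 by limma-voom and 1083 without fve-4 at 21 °C replicate 1. Without 1 library, total counts ranged from 3329 to 5077, 5918 to 7750, 11298 to 12310, 6306 to 8085 and 5502 to 6219 in the same order. Of 240 counts of list members by direction, 81 moved by over 1.5 times without some library; moves of 1 gene among fewer than 4 are not given singly. With an estimated correlation, camera called 0, 3, 3, 3 and 1 lists in that order, where the preset correlation called 4, 11, 11, 7 and 10. A higher correlation within lists does not account for all of this. The estimate was -0.01 for PIF and shade targets, whose camera adjusted p for the interaction went from 7.52e-06 to 0.0197. It was 0.01, as preset, for the FLC clade, which went from 0.00125 to 0.126 at 21 °C.

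The share of the left-out Col response kept by fve-4 was 48.8% for higher genes after median-ratio rescaling, and 55.4%, 49.1% and 46.4% without fve-4 replicate 1, 2 and 3. For lower genes it was 32.3% and 36% with pseudocounts of 0.1 and 5, 38.1% after median-ratio rescaling, 38.9% after quantile normalization, and 43.4%, 30.3% and 28.8% without fve-4 replicate 1, 2 and 3; the cause was not tested. Of 189 results for single named genes, 176 were called; 15 of these lost the call under some alternative, 13 of them without some library, and 4 results gained a call, with 0 reversed. SOC1 has 1 alternative fewer, since it did not pass the filter of 5 TPM.

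With the replicate number as a block, the counts were 4662, 7501, 12249, 7697 and 6353. The numbers do not pair the samples: over 18 pairs of libraries with the same number, residual correlations ranged from -0.14 to 0.19 with 1 over 0.1, and 5 of 12 libraries correlated best with their own number.

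Replicates differed by more than counting error, with chi-square per degree of freedom from 1.92 to 5.84, so counting error is not the whole spread between libraries; the source of the rest was not tested. Depth limits genes near 0, such as FT.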

Other observations

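The tests on deeper sequencing and on the share of root RNA, and the lists of sugar starvation, iron uptake and organelle genes, were chosen only after the result was seen. Genes that rise in plants short of sugar were high in Col at 27 °C and raised in fve-4 already at 21 °C. The list was prompted by ASN1, AT4G35770, BCAT-2 and UMAMIT33, which are left out here. Of the other 16 tested, 14 were higher and 0 lower in fve-4 at 21 °C (camera adjusted p = 4.91e-08), 16 rose in Col at 27 °C, 10 were lower and 0 higher in fve-4 at 27 °C, and 15 had a negative interaction. With an estimated correlation none of these passed camera (adjusted p = 0.166 for each). The list was not tested without single libraries. In fve-4 at 21 °C some members spread widely and others little, as GAT1_2.1 (6.36 ± 3.3 TPM) and TPS8 (48.1 ± 3.2 TPM). All plants were harvested at ZT13, in the dark, and sugar levels are not part of these data. MGL, a methionine-degrading enzyme, was at 17.3 ± 0.73 and 103 ± 5.9 TPM in Col at 21 and 27 °C, and at 30 ± 6.3 and 32.9 ± 2.9 TPM in fve-4 (SD, n = 3). SEN5 was at 347 ± 31 and 1870 ± 110 TPM in Col and at 686 ± 160 and 1690 ± 250 TPM in fve-4.

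Iron uptake genes without CYP82C4, named before the list was made, fell in Col at 27 °C, 19 of 21 with 1 higher (adjusted p = 6.91e-08, and 0.166 with an estimated correlation), and 14 had a positive interaction and 1 a negative one (0.241 with an estimated correlation). Root markers moved the same way, with 9 of 18 lower in Col at 27 °C and 12 of 18 higher in fve-4 at 27 °C, where 6 were higher without Col at 27 °C replicate 3 and 5 without fve-4 at 27 °C replicate 1. IRT1, the iron transporter of the root surface, was at 162 ± 18 and 12.7 ± 9.2 TPM in Col and at 73.1 ± 7.5 and 82.4 ± 26 TPM in fve-4; it is also one of the root markers. CYP82C4 was at 35.2 ± 3.5 and 0.759 ± 0.68 TPM in Col and at 9.29 ± 1.2 and 15.4 ± 3.1 TPM in fve-4. Of 73 chloroplast-encoded genes, 42 were lower and 2 higher in fve-4 at 27 °C (adjusted p = 7.29e-12, and 0.334 with an estimated correlation). In Col 33 rose at 27 °C and 3 fell, and 23 and 3 after median-ratio rescaling, but the list did not pass camera there (adjusted p = 0.0784). Of 23 mitochondrion-encoded genes 9 rose and 3 fell in fve-4 at 27 °C, and 6 and 4 after rescaling, without passing camera (adjusted p = 0.449). Neither organelle list was tested without single libraries. How the reads of organelle transcripts without a poly(A) tail entered the libraries is not stated.

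For the 4 comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05, and in each 1 split, the real one, called as many genes. The real split of the 6 libraries called 4619 genes for fve-4 against Col at 21 °C and 6810 at 27 °C, and 11911 for the warm response in Col, where the highest other split called 0 in each, and 7365 for that in fve-4, where the highest other split called 1.

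More genes were detected in fve-4. At equal read numbers (11000000 per library), Col libraries had 21252 to 21487 genes above 0 and fve-4 libraries 21717 to 22045, a mean difference of 449 (exact permutation p = 0.005, two-sided, over 400 regroupings, the smallest they can give). This argues against deeper sequencing of the fve-4 libraries. With at least 10 reads asked, the difference was 420 (exact permutation p = 0.005, the smallest possible), which argues against evenly spread background reads. Of 846 genes at 0 in all 6 Col libraries and above 0 in fve-4, 39 had at least 10 reads summed over the 6 fve-4 libraries, and 11 of the 846 had reads in all 6. Of 329 genes at 0 in all fve-4 libraries and above 0 in Col, 2 had at least 10 reads summed over the 6 Col libraries and 0 had reads in all 6. Some of the 39 genes rested mainly on fve-4 at 27 °C replicate 1, as JAL23 (80 of 97 reads) and THI2.1 (29 of 34). Others did not, as AT4G32630, with reads in all 6 fve-4 libraries (17 at 21 °C and 25 at 27 °C). A looser silencing of genes without FVE is a hypothesis that was not tested, and of the 3 genes in the list of silenced loci only 1, ROS1, was expressed enough to be tested. Other differences in tissue or stage between the genotypes stay open.

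The root markers lower at 27 °C in Col did not rest on one Col library, since without each Col library at least 6 were called lower. A smaller share of root RNA in Col at 27 °C may be a cause and cannot be told apart from a change within the root. Root hair markers had a median of -0.75 with 5 of 7 called lower, and endodermis markers a median of -0.14 with 0 of 5 called lower and 1 higher. The median change of 7 root hair markers minus that of 5 endodermis markers was -0.61 (exact permutation p = 0.091 over 792 regroupings). The ranges, -1.3 to 0.05 and -0.21 to 0.38, overlapped, so a smaller root share is not excluded.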
